A study of Mus musculus with 7 samples.

How the data were processed

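Brown fat total RNA of 3-day-old male mice had been extracted with Trizol, labelled with biotin and hybridised, 1 sample per array, per the labels' protocols. The deposited values are signal intensities, 1 per probe set and array, on a linear scale, and GCOS 1.2 is named in the submitters' processing notes. The scaling is not given in the sources used here. The deposited intensities had a mean, after trimming 2% at each end, of 500.003 on all 7 arrays, and array medians between 131.5 and 154, so this scaling was kept. The values came without detection calls in the table used here, so a probe set could not be called present or absent. The labels number the replicates but do not say that they are separate animals, so p-values measure the spread between these samples.

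The table held 45101 probe sets, of which 64 control probe sets were left out. Of the remaining 45037, the probe table gave 1 gene symbol for 34945, several for 932 and none for 9160. Symbols were updated through the gene identifiers of a RefSeq gene table (assembly GRCm38.p6), used for names and for which genes neighbour each other and not for coordinates, since no build is given with the array values. Genes were named from probe sets with 1 symbol. A probe set not listed in the probe table is called unnamed. The level of Gyk, fixed beforehand as a result, is not reported here, since 0 probe sets are paired with it.

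Values were analysed as log2(signal + 30.6), the offset being the 20th percentile of all values. A fold change on this scale understates the change of probe sets with low signal. Probe sets whose mean log2 value over all 7 arrays was under the 40th percentile were left out, irrespective of genotype, which left 27022 probe sets of 13102 genes. KO (n = 4) was compared with wild type (n = 3) by a linear model with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate or block was used. Means are of signals, with SD; log2 differences have their standard error (SE). Fits without an array kept the offset and the filter taken from all 7 arrays.

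The genes named were chosen by a rule: the 10 genes with the largest rise and the 10 with the largest fall among changed probe sets whose KO and wild-type arrays did not overlap (1 probe set per gene, the brightest that qualified; 0 clones or predicted genes had to be skipped), up to 4 members of each gene list by smallest p whether or not they passed, and any changed member of the thermogenesis and glycerol 3-phosphate lists. Members of a list that passed were also named. Of 877 gene entries in 34 lists, 746 had a tested probe set. The lists were tested with camera (preset correlation 0.01, 1 probe set per gene, the brightest) and again with an estimated correlation; fry was an alternative. Changed members were counted by the brightest probe set of each gene, with p-values adjusted over all probe sets tested and again adjusted over the list alone, so a member that passed on another probe set alone is not in these counts.

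The fit was tested on simulated data with 200 seeded changes over 27022 probe sets. With 4 KO and 3 wild-type arrays it recovered 44.8% of seeded log2 changes of 1, 89.6% of changes of 2 and 100% of changes of 3, with 6 false calls. With 3 against 3 arrays it recovered 62.7%, 77.6% and 95.5%, with 4 false calls. Camera called the 1 seeded list. Simulated genes varied independently, while list members could be correlated in the data (estimated correlation 0.49 for the glucocorticoid list and 0.43 for the cell cycle list). The simulation therefore does not test camera on correlated lists. Residual SDs were also dealt out at random over the probe sets, so the simulated data held no mean-variance trend. The recovery and the false calls therefore do not test the use of that trend, without which 6 probe sets passed in the data instead of 431.

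The design, the rule, the gene lists and most alternatives were fixed before the data were examined. The alternatives were quantile normalization, scaling by the array median, other offsets, filters and variance models, array weights, an unmoderated test, another threshold or criterion, 1 probe set per gene, the replicate number as a block and leaving out each array. Fits with the deposit block as a covariate, or within 1 block, were added after seeing the data. The position of an array between the genotypes was taken on signals, not on their logarithms. Array quality was checked by the ratio of 3' to 5' control probe sets (actin 1.14 to 1.39, Gapdh 0.765 to 0.876), correlations between arrays (0.948 to 0.975) and Xist and Y-linked genes. No pair of arrays held the same values.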

Results

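Gene expression was measured in the brown fat of 3-day-old male C57BL/6J mice that carried a knockout (KO) of Gyk, the gene of glycerol kinase, or were wild type. Glycerol kinase phosphorylates glycerol to glycerol 3-phosphate, from which triglycerides and phospholipids are built. Total RNA of 4 KO samples (replicates 1 to 4) and 3 wild-type samples (replicates 1, 3 and 4) had each been hybridised to 1 array of probe sets read out as signal intensities. The wild-type samples served as the control group. The array medians lay between 131.5 and 154 signal units and differed at most 1.17-fold. The number of arrays limits the precision of every value given here.

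The level of the targeted gene is not analysed here, because the probe table used here pairs it with 0 probe sets, so the genotype of each array rests on its label. On the first principal component, which held 35.3% of the variance, the wild-type arrays scored between -33.3 and -23 and the arrays of KO replicates 1, 3 and 4 between 33.4 and 35.7. The array labelled KO replicate 2 scored -13.8. Its highest correlation with any other array (0.975) was with wild-type replicate 1. Xist, the RNA of the inactive X chromosome, gave a signal of 893 on this array with 1 of its 3 probe sets and at most 13.1 on the other 6 arrays, although all samples were labelled male. The Y-linked gene Eif2s3y read 1252 on it against a mean of 1430 on the others, while 3 of the 4 brighter Y-linked probe sets read lower on it than on every other array. The second component (16.4%) separated wild-type replicate 1 and KO replicates 1 and 2 (21.8 to 24.5) from the other 4 arrays (-23.6 to -12.5). These sets of arrays were also deposited as separate blocks.

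**Figure D1:**
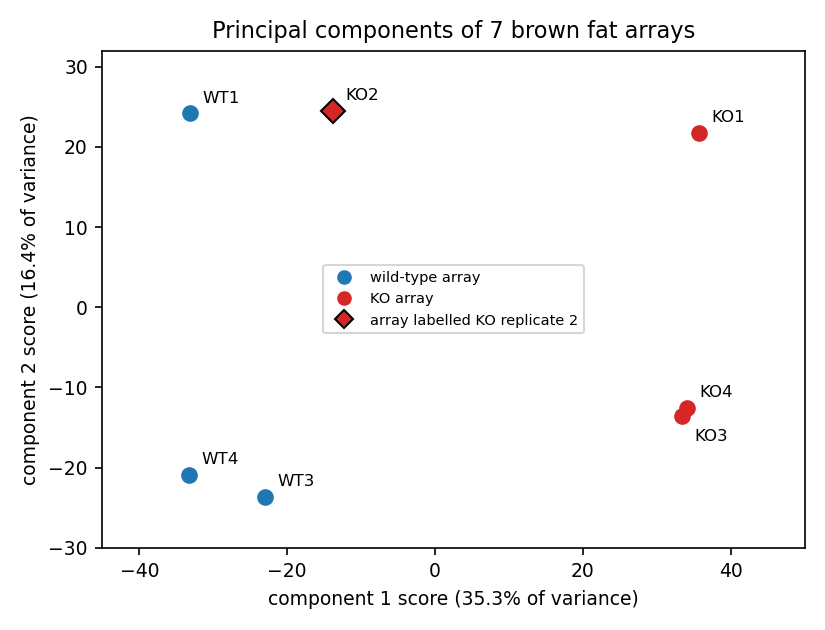
Scores of the 7 arrays (WT, wild type; KO, knockout; each with its replicate number) on the first component (x axis, 35.3% of the variance) and the second component (y axis, 16.4%). The array labelled KO replicate 2 scored -13.8 on the first component, on the side of the wild-type arrays, and 24.5 on the second.

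The comparison of KO with wild-type brown fat asked which transcripts change when glycerol kinase is lost. Cyp2b10, a cytochrome P450 of drug and steroid metabolism, rose most among the named genes, 30.1-fold, from 272 ± 247 (SD, n = 3) to 7865 ± 2900 (n = 4; log2 difference 4.91 ± 0.44, SE, adjusted p = 0.00274), and all 3 of its tested probe sets rose. Mycl, a transcription factor of the Myc family, rose 7.06-fold on 1 of its 3 probe sets, while the others (log2 differences 0.75 and 0.86) did not pass. Fmo2, a flavin-containing monooxygenase, rose 5.55-fold (3 of 4 probe sets passed), and Klf15, a transcription factor induced by glucocorticoids, rose 5.22-fold from 209 ± 62.4 to 1324 ± 593 (adjusted p = 0.0228). The other genes among the 10 largest rises were Acsm3 (4.64-fold), the sodium pump regulator Fxyd2 (4.52-fold), Chil3 (4.26-fold), Tmem252 (4.14-fold), the p53 target Trp53inp1 (4.07-fold on 1 of its 2 probe sets, the other at a log2 difference of 1.17 with adjusted p = 0.0965) and Igfbp3 (3.94-fold), which encodes a binding protein of insulin-like growth factors.

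Among the named genes the largest fall was that of Cxcl14, a chemokine, from 355 ± 160 to 38.5 ± 51.6 (log2 difference -2.67 ± 0.48, adjusted p = 0.0298), though its other probe set differed by -0.40 and did not pass. Genes of DNA replication and division made up 4 of the next 9: Mcm3 (4.11-fold lower, -2.04 on the log2 scale), Mcm5 (3.14-fold lower), the cyclin gene Ccnd1 (2.99-fold lower on this probe set, with 3 of 3 probe sets lower) and the ribonucleotide reductase gene Rrm2 (2.99-fold lower). The long noncoding RNA Neat1 was 4.06-fold lower, the imprinted gene Mest 3.45-fold lower (6084 ± 1110 to 1962 ± 1120), Masp1 3.29-fold lower, Iqsec1 3.21-fold lower and the pseudokinase gene Trib1 3.19-fold lower. For Mcm3, Mcm5, Rrm2, Neat1, Masp1, Iqsec1 and Trib1 the remaining tested probe sets did not pass, and those of Neat1 (-0.14) and Trib1 (-0.01) lay close to 0.

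**Figure D2:**
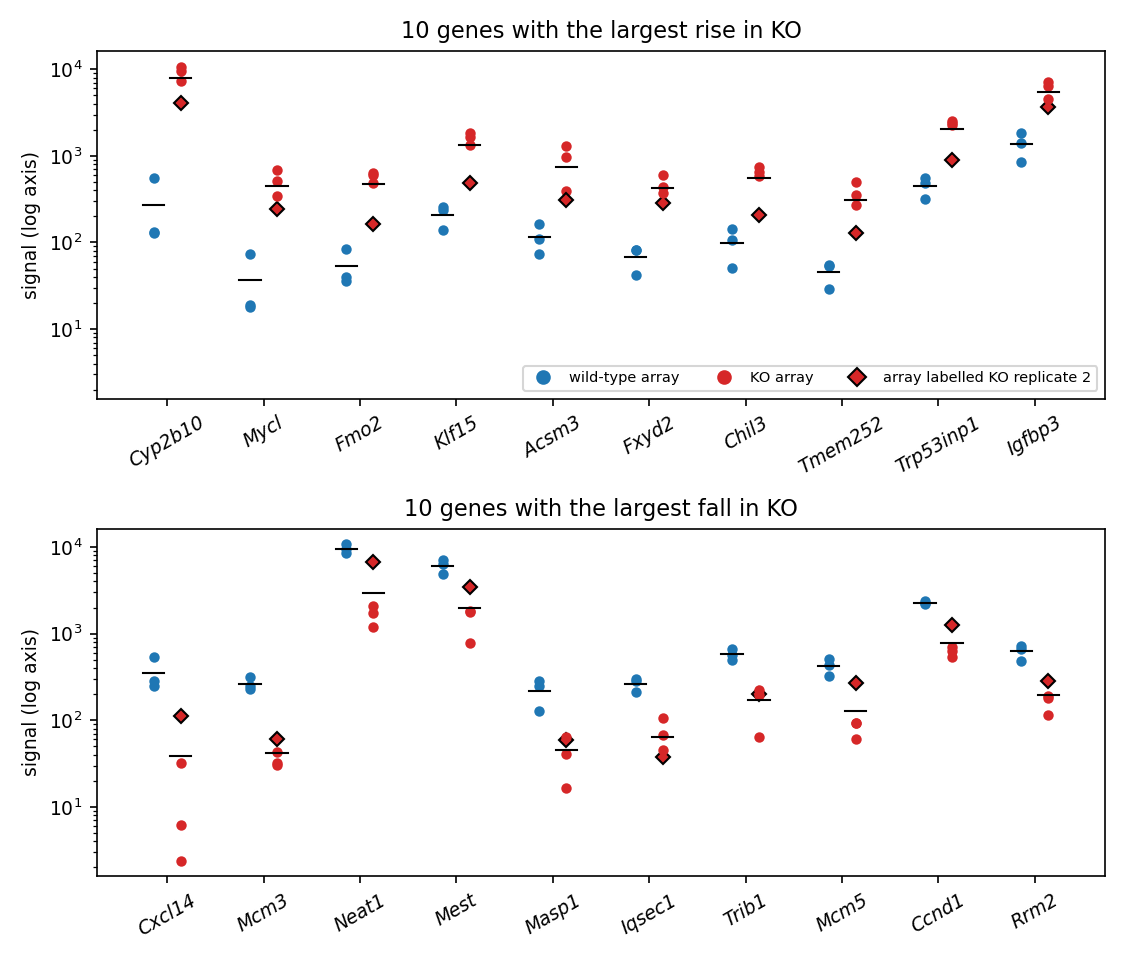
Signal of the 10 genes with the largest rise (upper panel) and the 10 with the largest fall (lower panel) on each array, on log axes, with a black line at each group's mean. By the rule that chose the 20 genes, no KO array overlaps a wild-type array in any of them. The array labelled KO replicate 2 is the KO array nearest to wild type in all 20 genes but Masp1, Iqsec1 and Trib1.

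In all, 431 of 27022 tested probe sets differed between KO and wild type (limma, Benjamini-Hochberg adjusted p under 0.05), 257 higher and 174 lower in KO. They represented 331 genes, 190 higher and 141 lower. At an unadjusted p under 0.05 there were 4465. In each of the 431 the KO and wild-type arrays did not overlap, as in 14.7% of all tested probe sets, against 5.71% by chance. The difference was at least 2-fold in 160. Without the array labelled KO replicate 2, 1986 probe sets passed, 848 higher and 1138 lower, and these included all 431 in the same direction. The count fell when any other array was left out, to 25, 8 and 7 without wild-type replicate 1, 3 or 4 and to 40, 9 and 15 without KO replicate 1, 3 or 4. With the deposit block as a covariate 631 passed. Within the second block alone (2 KO and 2 wild-type arrays) 726 passed. Within the first block alone, whose 1 wild-type array gives no spread within wild type, 0 passed.

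The largest changes also included unnamed probe sets. The 2 probe sets with the deepest fall, 1422703_at and 1422704_at, are unnamed here: 1422703_at fell 16-fold, from 7432 ± 1160 to 661 ± 798 (adjusted p = 0.0198), and 1422704_at fell 12.3-fold (adjusted p = 0.0277). In the array labelled KO replicate 2, 1422703_at read 1855, against 208 to 322 in the other KO arrays. Without the array labelled KO replicate 2 the log2 differences were -4.68 for 1422703_at and -4.37 for 1422704_at, against -4 and -3.62 with all arrays. The unnamed probe set 1448136_at rose 4.12-fold, from 1105 ± 222 to 4644 ± 883, with the smallest adjusted p of all (0.00253).

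The list of genes that respond to glucocorticoids was higher in KO. List members are counted here by their brightest probe set. Of 23 measured members of this list, 8 rose and 0 fell, and 15 rose when adjusted over the list alone. The risers included Klf15, the immunophilin gene Fkbp5 (3.49-fold, 575 ± 11.8 to 2248 ± 986), the transcription factor gene Zbtb16 (3.45-fold) and Cebpd (2.51-fold, 621 ± 40.2 to 1656 ± 502), a regulator of early fat cell differentiation. Per1, Tsc22d3, Cdkn1a and Sult1a1 also rose, by 1.78-fold to 2.56-fold. The median log2 difference over the list was 0.73 and the list stood above other genes (camera, adjusted p = 6.13e-13), but it did not pass with the correlation between its members estimated from the data (adjusted p = 0.52 with an estimated correlation). The list mean relative to wild type was 0.69 to 1.10 in KO replicates 1, 3 and 4 and 0.37 in the array labelled KO replicate 2. Without that array 14 members rose. Nfkbia and Klf9, 2 further members, passed on other probe sets alone, both higher. Such members, here and in other lists, were singled out after their values were seen.

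The list of cell cycle genes was lower. Of 36 measured members, 4 fell and 0 rose, and 22 fell when adjusted over the list alone. Rrm2 fell from 623 ± 128 to 194 ± 70.3, and Mcm2, a helicase subunit of DNA replication, fell 2.30-fold. Prc1, which organises the spindle midzone, fell 2.21-fold, and Mcm5 fell 3.14-fold. Top2a was 2.37-fold lower (adjusted p = 0.0613) and Tk1 3.46-fold lower (adjusted p = 0.0965), neither of which passed with all arrays. Both passed without the array labelled KO replicate 2 (adjusted p = 0.0043 and 0.0148). Top2a and Tk1 were named outside the rule, after their values were seen. The list median was -0.59 (camera adjusted p = 9.85e-13, adjusted p = 0.52 with an estimated correlation). Its mean on the array labelled KO replicate 2 was -0.32 against -0.91 to -0.70 on the other KO arrays, and without that array 14 members fell. Mcm3, also on the list, fell on a probe set other than its brightest.

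Neutrophil and myeloid granule markers were higher as a list (median 0.54, camera adjusted p = 5.33e-05, adjusted p = 0.52 with an estimated correlation). Of 10 measured members, 1 rose, Chil3, from 99.4 ± 45.7 to 550 ± 239, and 4 rose when adjusted over the list alone. Without the array labelled KO replicate 2, 3 rose. The antimicrobial peptide gene Camp was at 323 in KO against 94 in wild type (adjusted p = 0.0952) and Lcn2 at 471 against 222 (adjusted p = 0.102). Lcn2 passed with the deposit block as a covariate (adjusted p = 0.0286) and without the array labelled KO replicate 2 (adjusted p = 0.00859). The general macrophage and leukocyte markers had 0 of 24 members changed by the brightest probe set (median -0.11, camera adjusted p = 0.617), while Lyz1 rose on 1 other probe set (log2 difference 0.87, adjusted p = 0.0443) and 2 members rose without that array. Among the erythroid markers 0 of 10 changed (median -0.02, mean 0.04, camera adjusted p = 0.773).

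Fibroblast and extracellular matrix markers were lower as a list, with 0 of 29 members past the threshold by themselves and also 0 when adjusted over the list alone (median -0.29, camera adjusted p = 0.000593, adjusted p = 0.734 with an estimated correlation). The protease gene Fap was 1.99-fold lower (adjusted p = 0.0982) and the proteoglycan gene Lum 1.86-fold lower (adjusted p = 0.133), and both passed without the array labelled KO replicate 2 (adjusted p = 0.00595 and 0.00543). The list mean on the array labelled KO replicate 2 was 0.03, against -0.57 to -0.27 on the other KO arrays, and without that array 10 members fell. Ribosomal protein genes were higher as a list by a small amount (median 0.15; 0 of 35 changed, 0 adjusted over the list alone, camera adjusted p = 0.000315, adjusted p = 0.734 with an estimated correlation), and 1 rose without that array. Their list mean was 0.25 and 0.29 on KO replicates 3 and 4 and 0.09 on KO replicate 1. It was -0.04 on the array labelled KO replicate 2 and -0.05 to 0.05 on the wild-type arrays.

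**Figure D3:**
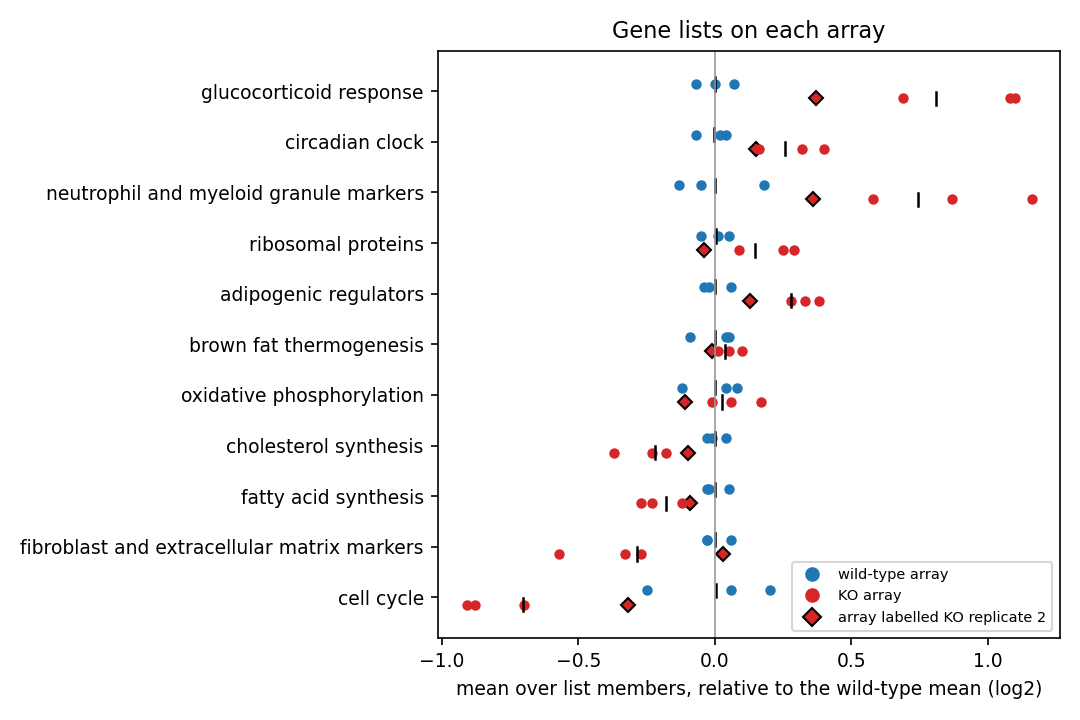
Mean over the measured members of 11 gene lists on each array, relative to the wild-type mean (x axis, log2), with a black line at each group's mean. Glucocorticoid response genes lay at 0.37 to 1.10 on the KO arrays and cell cycle genes at -0.91 to -0.32, while brown fat thermogenesis genes lay at -0.01 to 0.10.

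Of 22 measured genes of brown fat thermogenesis, 0 passed over all probe sets with all arrays and no covariate, and 2 were higher and 2 lower when adjusted over the list alone (median 0.02, camera adjusted p = 0.768). Letmd1, a mitochondrial protein gene, had the smallest p of the list (1.31-fold lower, 15430 ± 531 to 11750 ± 940, adjusted p = 0.0746) and passed with the deposit block as a covariate (adjusted p = 0.0497). Without the array labelled KO replicate 2, Letmd1 and Esrrg fell and Slc27a2 rose (adjusted p = 0.0288, 0.0492 and 0.0294). Ucp1, the uncoupling protein of heat production, was singled out after its values were seen: it read 30980 ± 2390 in wild type and 31510 ± 4630 in KO (log2 difference 0.02 ± 0.12), near the highest signals of the arrays, where an array can compress differences. Of oxidative phosphorylation genes 0 of 63 passed (median 0.04, camera adjusted p = 0.409), of tricarboxylic acid cycle genes 0 of 21 (median 0, mean -0.01, adjusted p = 0.874) and of fatty acid oxidation genes 0 of 28 (median 0.03, adjusted p = 0.435). Ehhadh, of peroxisomal oxidation, was at 8452 ± 3480 against 4026 ± 1440 and did not pass (adjusted p = 0.135), but did without the array labelled KO replicate 2 (adjusted p = 0.0153). Oxidative phosphorylation was called higher by camera without the array labelled KO replicate 2 (adjusted p = 0.0179, adjusted p = 0.783 with an estimated correlation) and within the second deposit block alone (adjusted p = 7.11e-06, adjusted p = 0.616 with an estimated correlation), with 0 of 63 members past the threshold without that array. Fatty acid oxidation was called within the second block alone (adjusted p = 0.0356, adjusted p = 0.679 with an estimated correlation), and 2 of its members rose and 1 fell without that array. In the first block the oxidative phosphorylation mean ran the other way, at -0.01 and -0.11 on KO replicates 1 and 2. It was 0.08 on wild-type replicate 1, the only wild-type array there.

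In glycerol 3-phosphate and triglyceride synthesis 1 of 20 measured genes changed, and 1 was higher and 2 were lower when adjusted over the list alone (median -0.06, camera adjusted p = 0.366). Lpin1, a phosphatidate phosphatase of triglyceride synthesis, rose 1.49-fold, from 6439 ± 382 to 9639 ± 1150 (adjusted p = 0.0393). Gpat3, an acyltransferase that uses glycerol 3-phosphate, was 2.31-fold lower (2523 ± 415 to 1191 ± 712) and did not pass (adjusted p = 0.092), but did without the array labelled KO replicate 2 (adjusted p = 0.00109), where 1 member rose and 1 fell. Mogat1 was 1.83-fold lower (adjusted p = 0.121). Among 24 genes of lipolysis and fatty acid uptake, Vldlr, the receptor of very low density lipoprotein, rose 1.45-fold and Lipa, the lysosomal acid lipase, fell 1.49-fold, while 4 rose and 3 fell when adjusted over the list alone and, over all probe sets, without the array labelled KO replicate 2 (median 0.06, camera adjusted p = 0.427). Fabp4 passed on 1 other probe set alone (log2 difference 0.48). Fabp3, a fatty acid binding protein, was at 11680 ± 4670 against 22240 ± 3860 (adjusted p = 0.0946) and passed with the deposit block as a covariate (adjusted p = 0.0168) and without the array labelled KO replicate 2 (adjusted p = 0.0179).

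Lipid synthesis lists were lower. Cholesterol synthesis (20 measured; 0 rose and 1 fell; 1 rose and 3 fell adjusted over the list alone) had a median of -0.23 (camera adjusted p = 0.0196, adjusted p = 0.52 with an estimated correlation), and Sqle, the squalene epoxidase, fell 1.85-fold from 438 ± 41.4 to 227 ± 52.1. Fdft1, which acts just before Sqle in the pathway, read 1768 in KO against 994 in wild type and did not pass (adjusted p = 0.118). Fatty acid synthesis (0 of 20 changed; 1 rose and 3 fell adjusted over the list alone) had a median of -0.26 (camera adjusted p = 0.0196, adjusted p = 0.52 with an estimated correlation). Fasn was 1.53-fold lower (adjusted p = 0.141) and Acacb 1.74-fold higher (adjusted p = 0.0572). Both passed with the deposit block as a covariate (adjusted p = 0.0368 and 0.0448) and without the array labelled KO replicate 2 (adjusted p = 0.0247 and 0.0327). Without the array labelled KO replicate 2, 3 cholesterol synthesis genes fell, and 4 fatty acid synthesis genes fell and 1 rose. Srebf2 fell on a probe set other than its brightest (log2 difference -0.73). Fatty acid synthesis did not pass within the second deposit block alone (adjusted p = 0.0615).

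Adipogenic regulators were higher as a list (20 measured; Cebpd and Klf15 rose and 0 fell; 3 rose adjusted over the list alone; median 0.06, camera adjusted p = 0.0344, adjusted p = 0.52 with an estimated correlation), as were circadian clock genes (17 measured; Per1 rose and 0 fell; 6 rose and 1 fell adjusted over the list alone; median 0.23, camera adjusted p = 0.0196, adjusted p = 0.52 with an estimated correlation). Cebpd, Klf15 and Per1 are also on the glucocorticoid list. Per2, another clock gene, was 2.10-fold higher (adjusted p = 0.071) and passed with the deposit block as a covariate (adjusted p = 0.037) and without the array labelled KO replicate 2 (adjusted p = 0.00847). Ebf1, an adipogenic regulator, passed on 2 of its 5 probe sets, each with a log2 difference of 0.63, but not on its brightest (0.61, adjusted p = 0.279), which passed with the deposit block as a covariate (0.74, adjusted p = 0.0248) but not without the array labelled KO replicate 2 (adjusted p = 0.117). In the fit without the array labelled KO replicate 2, 5 circadian clock genes and 3 adipogenic regulators rose.

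Of 16 adipokine and white fat associated genes, 3 fell and 1 rose, and 6 fell and 1 rose when adjusted over the list alone (median -0.11, camera adjusted p = 0.282). Rbp4, which encodes retinol-binding protein, fell 2.65-fold from 8581 ± 1970 to 3219 ± 691 (adjusted p = 0.0189). The imprinted gene Nnat fell 2.33-fold, as did Mest by 3.45-fold, and Igfbp3 rose. When the array labelled KO replicate 2 was left out, 7 fell. Igfbp3 was also the member that rose among 34 insulin and insulin-like growth factor signalling genes (0 fell; 1 rose adjusted over the list alone; median -0.03 and mean 0.03, camera adjusted p = 0.743), where 1 rose and 2 fell without that array. Igf1 was 2.16-fold lower on its brightest probe set (4983 ± 233 to 2524 ± 1380, adjusted p = 0.0979, or 0.00136 without the array labelled KO replicate 2), and 1 of its 4 tested probe sets passed. Foxo3 passed on 1 other probe set alone (log2 difference 0.78). In glycogen metabolism and gluconeogenesis (23 measured; 0 rose and 2 fell; 2 rose and 2 fell adjusted over the list alone; median -0.26, camera adjusted p = 0.221), Gys2, a glycogen synthase, fell 2.51-fold from 345 ± 81.1 to 121 ± 43.9 and Ppp1r3b, which targets a phosphatase to glycogen, fell 1.56-fold. Gyg rose on 1 other probe set alone (log2 difference 0.53, adjusted p = 0.0451), and without the array labelled KO replicate 2, 2 members rose and 5 fell.

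Of 26 p53 target and apoptosis genes, Trp53inp1 rose 4.07-fold and the cell cycle inhibitor gene Cdkn1a 2.07-fold, from 2749 ± 429 to 5802 ± 1400, and 0 fell (2 rose and 2 fell adjusted over the list alone; median 0.05, camera adjusted p = 0.351). When the array labelled KO replicate 2 was left out, 3 rose and 2 fell. Of 32 genes of the unfolded protein and amino acid stress response, Vldlr and Nupr1 (1.86-fold) rose and 0 fell, with 2 rising adjusted over the list alone (median 0.05, camera adjusted p = 0.366), and 4 rose and 1 fell without that array. Trib3 read 673 ± 288 against 327 ± 26.8 and did not pass (adjusted p = 0.141), but did without the array labelled KO replicate 2 (adjusted p = 0.0109). Among the remaining stress and immune lists, 0 members passed by the brightest probe set in the heat shock (of 13; median 0.14, camera adjusted p = 0.177), hypoxia (of 22; median 0.03; 0.984), oxidative stress (of 21; median 0.11; 0.298), interferon (of 24; median -0.16; 0.0793) and acute phase (of 18; median -0.03; 0.989) lists. Without the array labelled KO replicate 2, the heat shock list was higher by camera (adjusted p = 0.0113, adjusted p = 0.293 with an estimated correlation), with 3 members that rose. The interferon list was then lower (adjusted p = 0.0161, adjusted p = 0.514 with an estimated correlation), with 0 members past the threshold. In the same fit 2 hypoxia genes rose and 1 fell, 2 oxidative stress genes rose and 1 fell, and 2 acute phase genes rose. Nfkbia, an acute phase member, rose on 2 other probe sets (log2 differences 0.89 and 0.81), Mcl1 of the p53 list on 1 (0.50), and Higd1a of the hypoxia list fell on 1 (-1.16). With all arrays 0 members also passed for glycolysis (0 of 21; median -0.10, camera adjusted p = 0.274) and branched-chain amino acid breakdown (0 of 20; median 0.10; 0.0853), while without the array labelled KO replicate 2 there were 2 higher and 2 lower, and 2 higher and 1 lower. Adjusted over the list alone, 1 hypoxia gene fell, 1 oxidative stress gene rose and 1 fell, 2 acute phase genes and 2 of branched-chain amino acid breakdown rose, and 1 fatty acid oxidation gene rose.

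The remaining cell type lists held no member past the threshold and were not called by camera with all arrays. Endothelial (0 of 19; median -0.08, camera adjusted p = 0.302), Schwann cell (0 of 10; median -0.11; 0.659), keratinocyte (0 of 10; median -0.16; 0.703), hepatocyte (0 of 13; median -0.51; 0.282) and skeletal muscle markers (0 of 36; median 0.02; 0.897) held 0 changed genes. Adjusted over the list alone 1 Schwann cell gene rose and 1 fell, and 1 fell without the array labelled KO replicate 2. Skeletal muscle markers moved with the deposit block: their mean relative to wild type was 0.41 to 0.52 on the 3 arrays of the first block and -0.60 to -0.23 on the 4 of the second. Hepatocyte markers varied between arrays from -1.78 to 1.33 within and across genotypes. With the deposit block as a covariate, each of the 9 lists called above by camera passed again at the preset correlation, the largest adjusted p being 0.0287 (circadian clock). With the block and an estimated correlation they did not pass (camera adjusted p = 0.449 to 0.725).

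Within the second deposit block alone 8 of the 9 lists passed, all but fatty acid synthesis. Besides oxidative phosphorylation and fatty acid oxidation, camera called 5 more lists there. These were heat shock (adjusted p = 0.00279, adjusted p = 0.429 with an estimated correlation), branched-chain amino acid breakdown (adjusted p = 0.0105, adjusted p = 0.553 with an estimated correlation), adipokines (adjusted p = 0.0302, adjusted p = 0.429 with an estimated correlation), endothelial markers (adjusted p = 0.0406, adjusted p = 0.553 with an estimated correlation) and skeletal muscle markers (adjusted p = 0.0302, adjusted p = 0.616 with an estimated correlation). With an estimated correlation 0 of the 34 lists passed there, the smallest adjusted p being 0.429. Mixed fry, which asks for change in either direction, called 17 lists with all arrays (adjusted p = 0.00318 to 0.0236). Unlike camera, it does not compare a list with other genes. Since 4465 of 27022 probe sets had an unadjusted p under 0.05 in limma, a call by mixed fry does not set a list apart. They were 7 of the 9, all but the extracellular matrix and ribosomal protein lists, and 10 that camera did not call: thermogenesis, glycerol 3-phosphate and triglyceride synthesis, lipolysis, glycogen, branched-chain amino acid breakdown, insulin signalling, adipokines, oxidative stress, p53 targets and Schwann cell markers. By the brightest probe set, 17 list members that did not pass with all arrays passed with the deposit block as a covariate, and 0 were lost. Besides Letmd1, Fabp3, Acacb, Fasn, Ebf1, Lcn2 and Per2, these were Gpx3, Arntl, Ngp and Irs2, which were higher, and Pkm, Epas1, Gstm2, Birc5, Fbp2 and S100b, which were lower (adjusted p = 0.0272 to 0.0479). Irs2, Birc5 and Fbp2 were named after their values were seen.

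**Figure D4:**
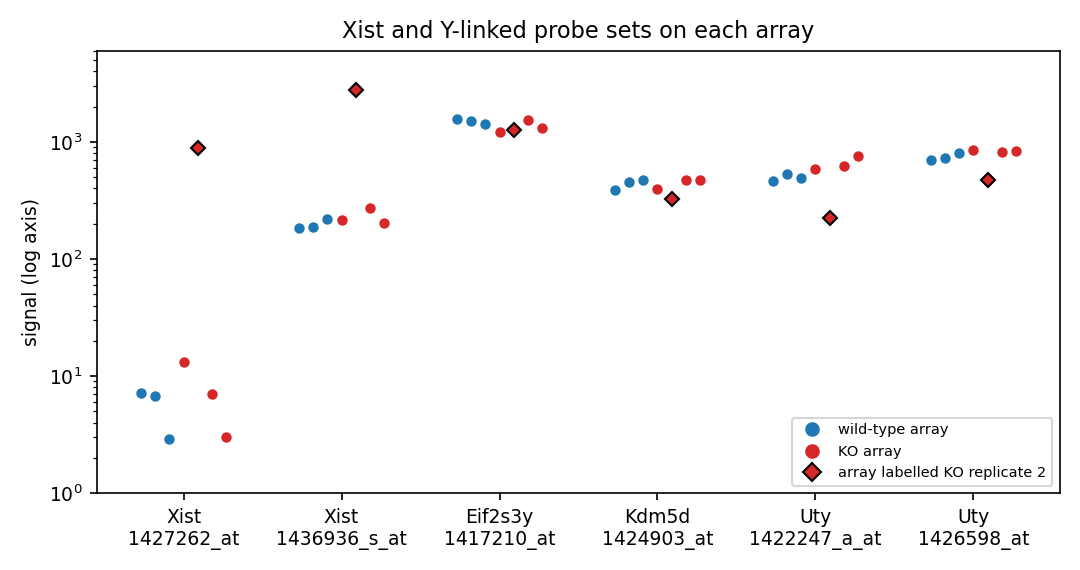
Signal of the 2 probe sets of Xist over 200 on the array labelled KO replicate 2 and of the 4 probe sets of the Y-linked genes Eif2s3y, Kdm5d and Uty with a mean over 200 on the other arrays, on a log axis, in the order wild-type replicates 1, 3 and 4 and KO replicates 1 to 4. Xist read 893 and 2757 on the array labelled KO replicate 2 and at most 13.1 and 273 on the others, while the Y-linked probe sets shown read 224 to 1252 on it.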

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

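All tests in this part were chosen after the results were seen. In each of 190 measures the 4 KO arrays were compared for 1 array far from the other 3, by the gap to the nearest array over the whole range; 13 stood out, where chance gives about 1 in 20, or 9.5. Xist was entered by the 2 of its 3 probe sets that read over 200 on the array labelled KO replicate 2. Their flags were thus favoured by this choice, and the 13 includes them. The third Xist probe set read 93 on that array against at most 43.5 on the others and was not entered. Of the 13, 8 concerned the array labelled KO replicate 2. They were its score on the first component (ratio 0.954), 2 probe sets of Xist (0.989, signal 893, and 0.972, signal 2757), the brightest probe set of Uty (0.918; 475 against 823 to 854), Trp53inp1 (0.894; log2 signal 9.85 against 11.2 to 11.3), Slc27a2 (0.882), Mcm2 (0.849; 8.94 against 8.03 to 8.16) and the heat shock list mean (0.867; -0.11 against 0.28 to 0.34). KO replicate 1 stood out in Trib1 (0.884; 6.57 against 7.83 to 8) and in the mean of the glycerol 3-phosphate and triglyceride synthesis list (0.833; -0.17 against -0.12 to -0.11). KO replicate 3 stood out in Fdft1 (0.953; 11.5 against 10.5) and Krt14 (0.967), and KO replicate 4 in the mean of the lipolysis list (0.833; 0.11 against -0.01 to 0.01).

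The array labelled KO replicate 2 lay between the genotypes. On the 500 probe sets of smallest p and at least 2-fold difference in a fit without it, its median position was 33.7% of the way from wild type to the other KO arrays, with quartiles of 17% and 52.3%; wild-type arrays placed in the same way, each without itself, lay at 3.6% to 16.1%, which argues against a wild-type animal under a KO label. The position on signals had a median of 22.1% over glucocorticoid response probe sets and 49.6% over cell cycle probe sets. It was 77.8% for 1422703_at and 64.7% for 1422704_at. For the same place on the log scale, a position on signals lies nearer wild type for a rise than for a fall. Glucocorticoid members rose while cell cycle members and these 2 probe sets fell, so the scale could give such differences by itself. Positions on the log scale were not taken, and the 33.7% is a median over rises and falls. If RNA of a wild-type female were the whole cause, the Y-linked probe sets should read about 33.7% of the other arrays, and their median was 66.8% (38.9% to 87.5% over the 4 probe sets with a mean signal over 200, SD 20.7, and 61.4% to 148% over the 5 dimmer ones, which were not used), which leaves this open, and a smaller share of such RNA as part of the cause was not tested. A male with a second X chromosome would carry Xist (893 against at most 13.1) and Y-linked genes together, but 3 of the 4 Y-linked probe sets lay below every other array, and these possibilities cannot be told apart here; a milder response of this animal to the knockout was not tested.

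The splits of the arrays show the same structure. Of the 35 splits of the 7 arrays into 3 and 4, 2 gave as many changed probe sets as the real one (431), as many higher (257) and as many lower (174), so chance cannot be excluded by this count. The other split set KO replicates 1, 3 and 4 against the 3 wild-type arrays and the array labelled KO replicate 2, and gave 1858 probe sets, 1111 higher and 747 lower in the group of 4. That is several times the real count and points to a structure of the samples. The next split gave 7. Without that array, 1 of the 10 splits of the 6 arrays, the real one, gave 1986 probe sets, and the highest of the others was 2; 10 splits are too few for a share under 0.05.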

How the results depend on the processing

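The deposit block fits were chosen after seeing the data; the other alternatives were planned. The count of changed probe sets, 431 (257 higher, 174 lower), was 235 (158 and 77) when each array was divided by its median, 100 (64 and 36) with no filter on dim probe sets, where more probe sets share the adjustment, and 6 (3 and 3) without a mean-variance trend. Array weights gave 1312 (630 and 682), with a weight of 0.56 for the array labelled KO replicate 2, and a threshold of 0.1 gave 1085 (567 and 518). An unmoderated test gave 0 (0 and 0), with 3801 at an unadjusted p under 0.05, against 431 and 4465 in limma. Leaving out 1 array gave between 7 and 1986 (7 to 848 higher, 0 to 1138 lower). With the deposit block as a covariate 293 were lower; with the covariate and without the array labelled KO replicate 2 there were 2330 (1005 and 1325). The second block alone gave 726 (375 lower), and the first alone 0 (0 and 0), where the lone wild-type array is assumed to vary like the KO arrays. Beyond the effect of fewer arrays or more tests, the cause was not tested. Quantile normalization, other offsets, a stricter filter, a robust fit, an added 1.5-fold criterion and 1 probe set per gene kept all counts within 1.5 times. No setting moved the median of all probe sets by over 0.03.

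Of the 36 named genes past the threshold, 0 reversed under any setting in which they were tested. With an offset of 1, 34 of them were tested, and with the stricter filter 26. All 36 passed without the array labelled KO replicate 2 and with the deposit block, which added 14 named genes; 1 to 11 passed when 1 of the other arrays was left out, 9 without the filter and 2 without a trend.

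Camera called 9 lists, and between 6 and 13 in most settings. In the second deposit block alone it called 15, or 0 with an estimated correlation there. With an estimated correlation and all arrays it called 0, and directional fry called 0. Mixed fry, which asks for change in either direction and does not compare a list with other genes, called 17. Skeletal muscle markers reversed in the second block alone (0.0302), and oxidative phosphorylation (5.44e-06) and ribosomal proteins (0.627) in the first alone, where 1 wild-type array cannot settle a direction.

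With the replicate number as a block over replicates 1, 3 and 4, 2173 probe sets changed (940 higher, 1233 lower), against 1986 (848 and 1138) without the replicate block on the same 6 arrays. Same-numbered arrays deviated together with correlations of 0.14, 0.09 and 0.11, not all over 0.1, so the numbers were not taken as pairs. Other combinations gave -0.08 to -0.03. Deviations from a group mean cancel out within the group, so positive same-number values make the others negative on average. The negative values are therefore no separate evidence of pairing. Every array correlated best with its own number, at most a hint from the data. For number 1 the deposit block cannot be told apart from pairing. Wild-type replicate 1 and KO replicate 1 were the only arrays of the first block among these 6. Signals near the offset of 30.6 limit what can be seen in dim probe sets.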

Other observations

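The genes in this paragraph were chosen after their values were seen. Single genes outside the lists passed the threshold, and they were not tested as a group. Among those higher in KO were the glutamine and alanine transporter gene Slc38a2, 2.66-fold (1550 to 4303; adjusted p = 0.0198, limma), the proline dehydrogenase gene Prodh, 3.39-fold (292 to 1114; adjusted p = 0.0198), the glutamine synthetase gene Glul, 1.95-fold on its brighter probe set (6582 to 12740; adjusted p = 0.0277) and 2.79-fold on the other, and the taurine transporter gene Slc6a6, 2.44-fold on 1 of its 3 probe sets, which is not the brightest (adjusted p = 0.0362). The glucose transporter gene Slc2a3 rose 2.84-fold (294 to 948; adjusted p = 0.0342). Beside Cyp2b10 and Fmo2, Cyp2e1 rose 2.41-fold (901 to 2278; adjusted p = 0.0364) and Fmo1 1.85-fold (3591 to 6678; adjusted p = 0.0204), both of oxidative drug metabolism. Srsf3, a splicing factor, fell on 5 of its 6 tested probe sets, by 1.81-fold to 3.14-fold. The creatine kinase gene Ckb fell 2.83-fold (3920 to 1372; adjusted p = 0.0298), the basement membrane gene Nid2 2.37-fold (adjusted p = 0.0371) and, on 2 of its 4 probe sets, the actin-bundling gene Fscn1. These were its dimmer probe sets (1.92-fold, adjusted p = 0.0403, and 3.68-fold, adjusted p = 0.0298), and the brighter ones were 2.13-fold and 1.40-fold lower and did not pass.

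All tests below were chosen after the results were seen. Neutrophil and myeloid granule markers were higher in KO, by 0.59 (log2) over the 9 members besides Chil3 (exact permutation p = 0.0571, two-sided; the smallest possible is 0.0286). More blood in the KO samples would raise erythroid markers alike, and these differed by 0.04, below the neutrophil difference by more than their spread. This argues against a larger amount of blood as the sole source. The error of the neutrophil difference was not counted, and more neutrophils in the same amount of blood was not tested. Relative to S100a8 and S100a9, Chil3 was higher in KO by 1.57 (log2; exact permutation p = 0.0571), which leaves open whether more neutrophils alone account for its rise. A change within myeloid cells stays open and was not tested.

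Mest, Nnat and Ndn are imprinted genes, and all 3 were lower in KO (Ndn on 1 of 8 tested probe sets, 1.79-fold; adjusted p = 0.0446). The hypothesis that imprinted genes fell together was tested on 23 other measured imprinted genes. Of these, 0 passed in limma with all arrays and 1 without the array labelled KO replicate 2; their median was -0.11 (SD 0.35), and 15 of the 23 lay below 0. The mean of the 3 was -1.22 by the brightest probe set of each, which for Ndn did not pass (-0.66), and the 3 were picked because they were lower. A fall of that size was not seen across the others, and a smaller shared fall stays open.

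Neighbours of the targeted gene were counted for an excess of changes. Of the 30 nearest measured neighbours of the targeted gene on the X chromosome, 2 (6.67%) changed with all arrays, against 2.52% of other genes (Fisher's exact p = 0.175), and 4 (13.3%) against 10.9% without the array labelled KO replicate 2 (Fisher's exact p = 0.564). Both shares lay above those of other genes and neither difference passed, so an excess stays open. Prrg1 was the neighbour with the largest change, 3.87-fold on 1 of its 3 probe sets (39.3 to 249; adjusted p = 0.0189), while its other probe sets differed by -0.07 and 0.24.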
